A study of Mus musculus with 6 samples.

How the data were processed

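Cerebral cortex of F2 mice was collected at 6 weeks of age, and poly(A) libraries were made with a directional kit, per the labels. The submitters' processing notes name bcl2fastq 2.19, fastp 0.23.4, HISAT2 2.2.1 and StringTie 2.2.1, and the genome build GRCm39, without roles or order. The annotation release, the strand setting and the way StringTie output became counts per gene are not given in the sources used here. The deposited values are whole-number counts per Ensembl gene, not normalized, with 1 column per library, and the authors paired identifiers with gene symbols in the same table. Of 33274 gene rows, 985 had no symbol, and these held at most 0.175% of the counts of a library. Where 1 symbol had several rows, as 59 symbols did, the row with the highest mean count was used for gene lists.

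Groups came from the sample labels, and 3 libraries of each lineage entered the comparison. The labels do not say which animals shared a litter or a sire, so p-values measure only the spread between these samples. Total counts were 26914606, 25434152 and 24000528 in saline replicates 1 to 3 and 23896752, 28120640 and 24598669 in methylphenidate replicates 1 to 3. A count of 0 allows up to 3 counts, which was 0.106 to 0.124 CPM in a library, for counting error only. Mitochondrially encoded genes took 6.44 to 8.19% of the counts and Rn18s-rs5 0.129 to 0.621%. Gm10925, a nuclear copy of mitochondrial sequence, had 100.2 to 102.7% of the counts of mt-Atp6 in each library. Reads of near-identical copies thus appear to have been counted at both, which was not traced, and genes with such copies are uncertain. Libraries of one group differed by 13.0 to 19.9 times the sampling noise (chi-square per degree of freedom over genes with 20 or more counts), so no library was a duplicate of another of its group.

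Counts were analysed in R 4.3.3 with edgeR 4.0.16, which used filterByExpr at its defaults, TMM scaling and the quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are methylphenidate minus saline, and their standard errors were taken as the fold change divided by the square root of the F statistic. CPM values used TMM-scaled library sizes. Of the genes, 18327 were tested. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over all 45 lists with 5 or more tested members of the 46 fixed, pathway and cell type lists together.

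The gene lists, the tests, the alternatives marked as planned and the rule for named genes were chosen before the data were examined. The rule took the genes past the threshold with non-overlapping groups, a mean of at least 1 CPM in the higher group and an informative symbol, at most 10 in each direction. Where fewer than 10 qualified, it filled a direction up to 5 with the genes of smallest p, given as values only. It also took up to 4 tested members of smallest p in each described list, the sex-linked transcripts, and 9 core genes of methylphenidate action and neuronal activity. Blcap, A930015D03Rik, Mir7080 and Gm20394 were added for their overlap with called genes, and H2-T10, H2-D1, H2-K1, Ttr, Pomc, Avp, Foxp1 and Septin2 after their values were seen. Some genes that the rule takes are not reported here.

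Alternatives were RLE, upper-quartile and total-count scaling, no filter and a stricter filter (10 counts in 3 libraries and a mean of 1 CPM), a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, robust and older forms of the edgeR fit, other thresholds, library sizes without mitochondrially encoded genes, and, for lists, an estimated correlation, fry and cameraPR. After the data were seen, the striatal list mean of each library was added as a covariate, and lists were tested without the members they share with the striatal list. Genes near each other were found with the GENCODE M21 annotation of GRCm38, which differs from the build of the counts, and it was used only for which genes neighbour or overlap each other.

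The analysis was tested on simulated data with 200 changed genes among 17946 tested in a simulation of methylphenidate against saline. The share of changed genes recovered was 25.4% at a 1.5-fold change, 56.7% at a 2-fold change and 81.8% at a 4-fold change, and 8 of 117 calls were false. A seeded list of 20 genes raised by 0.5 on the log2 scale was called, and 1 of 40 unchanged lists was. The simulated genes were drawn independently of each other, while the estimated correlation between genes of a real list reached 0.94. The simulation therefore does not show how often camera calls unchanged real lists.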

Results

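Gene expression was measured by RNA-seq in the cerebral cortex of 6 female ICR mice, an outbred stock, at 6 weeks of age. The mice were grandoffspring of males that had received methylphenidate, a blocker of the dopamine and noradrenaline transporters, at 15 mg/kg, or saline at 10 mL/kg, under the skin for 21 days. The treated males were mated with untreated females, and F1 males were mated with untreated females in turn, so that the cortex samples came from animals that were never dosed themselves. There were 3 libraries in the saline lineage and 3 in the methylphenidate lineage. The total count per library lay between 23896752 and 28120640 over 33274 gene rows. The comparison asked whether cortical expression in grandoffspring differed with the treatment of the grandsire.

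Xist, the RNA that coats the inactive X chromosome, had between 22761 and 27480 counts in each of the 6 libraries. Its antisense transcript Tsix had 1 to 5 counts per library, and the Y-linked gene Uty had at most 2 counts in any library. Ddx3y, Kdm5d and Eif2s3y had no row in the counts used here and could not be analysed. These levels are those of female tissue in both groups, as labelled.

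Expression of 5 genes differed between the lineages, with 4 higher and 1 lower in the methylphenidate lineage. Firre (ENSMUSG00000085396), an X-linked long noncoding RNA that takes part in nuclear organisation, fell by 4.27 on the log2 scale (SE 0.24), from 51.4 ± 10.3 CPM in the saline lineage to 2.64 ± 0.97 CPM (SD, n = 3 per group; edgeR adjusted p = 0.000196). Nnat (ENSMUSG00000067786), an imprinted gene for a membrane proteolipid of developing neurons, rose by 1.11 (SE 0.10), from 51.8 ± 6.8 to 112.1 ± 8.6 CPM (edgeR adjusted p = 0.00776). Cpne7 (ENSMUSG00000034796), which encodes a calcium-dependent phospholipid-binding copine, rose by 1.00 (SE 0.10), from 25.3 ± 2.7 to 50.6 ± 3.1 CPM (edgeR adjusted p = 0.0119). H2-T23 (ENSMUSG00000067212), a nonclassical major histocompatibility class I gene, rose by 2.10 (SE 0.24), from 1.14 ± 0.13 to 4.92 ± 0.17 CPM (edgeR adjusted p = 0.0269). Hap1 (ENSMUSG00000006930), which encodes huntingtin-associated protein, rose by 0.93 (SE 0.11), from 65.3 ± 1.6 to 124.5 ± 19.8 CPM (edgeR adjusted p = 0.0277).

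**Figure D1:**
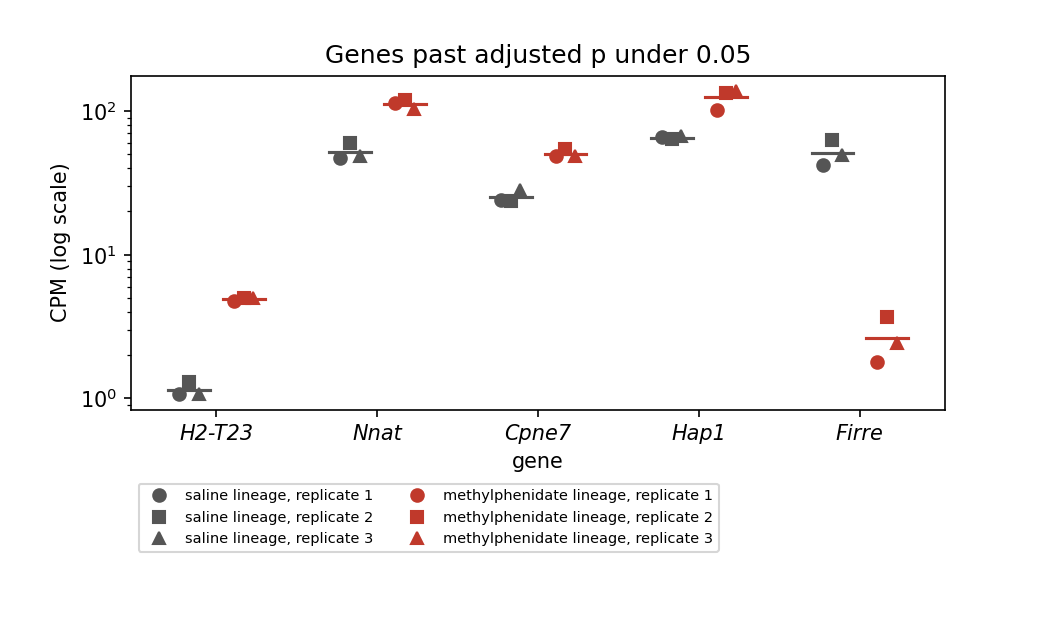
CPM on a log scale for the 5 genes past the threshold, with one point per library, the marker shape giving the replicate and the line the mean of the 3 libraries of a group. In each gene the 3 libraries of one lineage lie apart from the 3 of the other, and Firre lies at 42.4 to 62.6 CPM in the saline lineage and 1.78 to 3.69 CPM in the methylphenidate lineage.

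The groups did not overlap in any of the 5 genes. Over the whole table, the groups did not overlap in 2471 of 18327 genes tested, or 13.5%, where chance gives 10%. At an unadjusted p under 0.05 there were 1376 genes, 769 higher and 607 lower, where 916 were expected by chance. The median standard error of a log2 fold change was 0.15. The calls of Firre and Nnat held without any one library, with edgeR adjusted p at most 0.00543 for Firre and 0.0347 for Nnat. The call of Cpne7 was lost without saline replicate 1, saline replicate 2 or methylphenidate replicate 3 (edgeR adjusted p 0.0622 to 0.0766). The calls of H2-T23 and Hap1 were each lost without any one saline library, methylphenidate replicate 2 or methylphenidate replicate 3 (edgeR adjusted p 0.0582 to 0.119 for H2-T23 and 0.0582 to 0.161 for Hap1). The count of genes past the threshold was 3 without saline replicate 2 and 8 without saline replicate 3. It was 26, 12 and 2 without methylphenidate replicates 1, 2 and 3. Without a filter on low counts H2-T23 and Hap1 were not called (edgeR adjusted p 0.0534 and 0.124). With the striatal list mean of each library as a covariate, a model chosen after the data were seen, Firre alone of the 5 stayed past the threshold (edgeR adjusted p = 0.0105), and Nnat, Cpne7, H2-T23 and Hap1 had edgeR adjusted p of 0.0690, 0.181, 0.847 and 0.847. Their log2 fold changes were then 1.35 (SE 0.16), 1.19 (SE 0.17), 2.16 (SE 0.42) and 0.95 (SE 0.19), none of them smaller than without the covariate. Since the 5 genes were called in these same libraries, the covariate could hardly remove them. It does not decide whether striatal tissue plays a part. DESeq2 called 149 genes, 105 higher and 44 lower, among them the same 5.

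H2-T23 belongs to a family of near-identical genes whose reads can be shared, so its level is uncertain. H2-T10, a gene of the same family chosen after its values were seen, had 616, 530 and 565 counts in the saline libraries and 249, 21 and 224 in the methylphenidate libraries (log2 fold change -1.75, SE 0.60, edgeR adjusted p = 0.555). H2-D1 and H2-K1, class I genes also chosen after their values were seen, had log2 fold changes of 0.57 (SE 0.10, edgeR adjusted p = 0.146) and 0.82 (SE 0.42, edgeR adjusted p = 0.716). In the GENCODE M21 annotation of GRCm38, Nnat overlaps Blcap, H2-T23 overlaps A930015D03Rik, Cpne7 overlaps Mir7080 and Hap1 overlaps Gm20394, and since the strand setting of the counting is not given in the sources used here, reads of such pairs cannot be told apart here. A930015D03Rik had a log2 fold change of 1.07 (SE 0.58, edgeR adjusted p = 0.737), Mir7080 had 3 counts in each group, and Gm20394 had 7 in the saline and 17 in the methylphenidate lineage. Blcap had a log2 fold change of 0.12 (SE 0.07, edgeR adjusted p = 0.765).

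The genes next in order of p did not pass the threshold. U2surp, a component of the U2 spliceosome, had a log2 fold change of 0.70 (SE 0.09, edgeR adjusted p = 0.0703). Ndor1 (ENSMUSG00000115018) had a log2 fold change of -2.12 (SE 0.28, edgeR adjusted p = 0.0703), but the table holds 3 identifiers for this symbol, and their summed counts were 692, 590 and 685 in the saline libraries and 721, 869 and 706 in the methylphenidate libraries. Mdfic2 had a log2 fold change of -1.02 (SE 0.15) and Igfbp4, an insulin-like growth factor binding protein gene, one of -0.61 (SE 0.10), with edgeR adjusted p of 0.0912 and 0.111.

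Genes fixed for their part in the action of methylphenidate and in neuronal activity did not pass the threshold. The dopamine receptor genes Drd1 and Drd2 had log2 fold changes of 0.98 (SE 0.21, edgeR adjusted p = 0.226) and 2.86 (SE 0.78, edgeR adjusted p = 0.389). Th, the rate-limiting enzyme of dopamine synthesis, had a log2 fold change of 0.17 (SE 0.59). Bdnf, a neurotrophin gene, had one of -0.04 (SE 0.11). The activity-induced genes Fos, Arc and Egr1 had log2 fold changes of -0.21 (SE 0.23), -0.29 (SE 0.37) and -0.57 (SE 0.20), with edgeR adjusted p of 0.885, 0.902 and 0.569. The transporter genes Slc6a3 and Slc6a2, whose proteins methylphenidate blocks, had at most 5 and 3 counts in any library. They lay below the expression filter, so no difference could be tested. The data do not tell whether depth or the tissue set these low counts.

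Of the 45 gene lists tested, 11 passed camera at a preset correlation of 0.01, 7 higher and 4 lower in the methylphenidate lineage, and 6 of them were marker lists of cell types. No list passed when the correlation between genes was estimated, where 2 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.632. The rotation test fry, which asks whether the genes of a list move on balance one way, called 2 lists, the serotonin signalling and imprinted genes lists, which camera did not call. The count of lists past camera was 6 without saline replicate 1, 6 without saline replicate 3, 7 without methylphenidate replicate 1 and 5 without methylphenidate replicate 3.

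The striatal projection neuron list, which holds genes of the medium spiny neurons below the cortex, was higher in the methylphenidate lineage, with a median log2 fold change of 0.97 over 12 tested members, 11 of them above 0 (camera adjusted p = 4.05e-06; adjusted p = 0.632 with an estimated correlation). No member passed over all genes tested, and 9 were higher adjusted over the list alone. Pde10a, a phosphodiesterase gene of these neurons, had a log2 fold change of 1.17 (SE 0.24), from 49.9 ± 9.0 to 112.2 ± 40.0 CPM. Six3, a homeobox gene, had one of 3.02 (SE 0.67). The mean centred log2 CPM of the list was 0.75, -0.03 and 1.13 in methylphenidate replicates 1, 2 and 3 and -0.15, -0.80 and -0.89 in saline replicates 1, 2 and 3. The call held without any one library, and the list median then lay between 0.63, without methylphenidate replicate 3, and 1.32.

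The hypothalamic and basal forebrain list was also higher, with a median log2 fold change of 2.06 over 8 tested members, all 8 above 0 (camera adjusted p = 4.05e-06; adjusted p = 0.632 with an estimated correlation). No member passed over all genes tested, and 4 were higher adjusted over the list alone. Trh, which encodes thyrotropin-releasing hormone, had a log2 fold change of 3.05 (SE 0.59), from 0.35 ± 0.23 to 2.97 ± 1.66 CPM. The cholinergic genes Slc5a7, Slc18a3 and Chat had log2 fold changes of 2.13 (SE 0.45), 2.45 (SE 0.55) and 1.99 (SE 0.74). These 4 genes lay at a mean of no more than 3.94 CPM in either group. The list mean was 0.90, 0.26 and 1.57 in methylphenidate replicates 1, 2 and 3, all above the saline libraries. The striatal list means of these replicates, 0.75, -0.03 and 1.13, followed the same order. In the saline lineage replicate 1 was highest in both lists, while replicates 2 and 3 were ordered differently. Whether both lists reflect the same source was not tested.

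**Figure D2:**
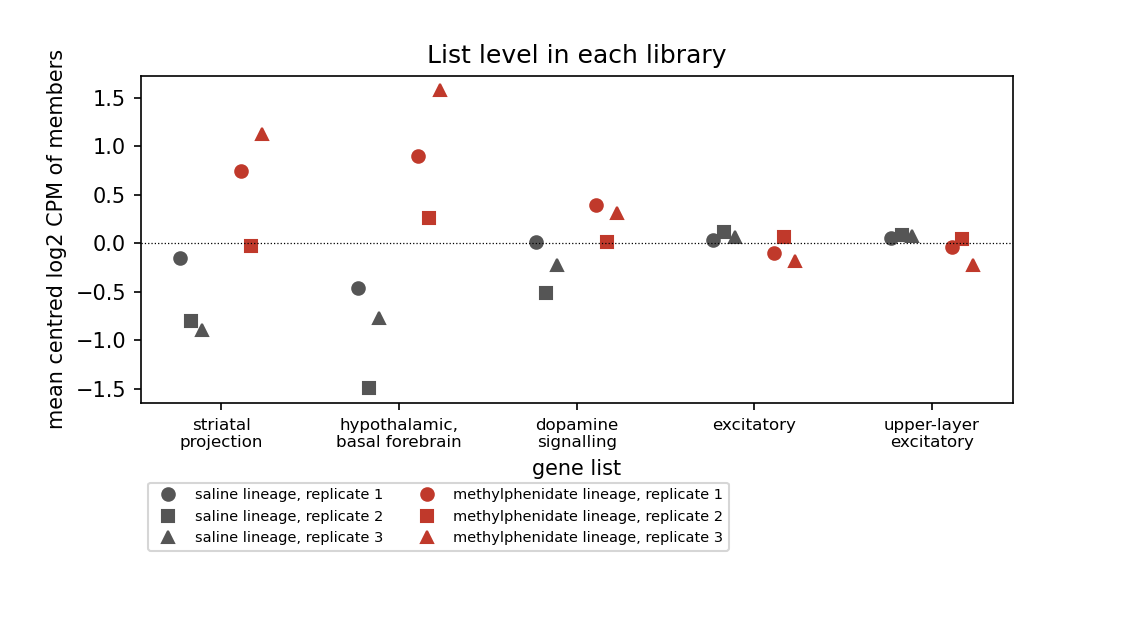
Mean over the tested members of log2 CPM, each gene centred on its mean over the 6 libraries, for 5 gene lists, with one point per library and the marker shape giving the replicate. In the striatal list, methylphenidate replicates 1 and 3 lie at 0.75 and 1.13 and methylphenidate replicate 2 at -0.03, near saline replicate 1 at -0.15.

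The dopamine signalling list was higher, with a median log2 fold change of 0.18 over 13 tested members, 10 of them above 0 and 3 below (camera adjusted p = 0.0356; adjusted p = 0.739 with an estimated correlation). None passed over all genes tested, and 3 were higher adjusted over the list alone. Its members with the smallest p were Drd1, Drd2, Ppp1r1b and Adcy5, a striatal adenylyl cyclase gene with a log2 fold change of 0.66 (SE 0.17), and 3 of these 4, all but Adcy5, are also in the striatal list. Without the 3 shared members the dopamine list had a median of 0.17 and a camera adjusted p of 0.329. The call was also lost without saline replicates 2 or 3 or methylphenidate replicates 1 or 3 (camera adjusted p 0.0695 to 0.268) and without a filter on low counts (camera adjusted p = 0.0592), and the median was 0.32 without methylphenidate replicate 3.

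The neuropeptide list was higher, with a median log2 fold change of 0.25 over 18 tested members, 12 of them above 0 and 6 below (camera adjusted p = 0.0138; adjusted p = 0.632 with an estimated correlation), and none passed over all genes tested while 2 were higher adjusted over the list alone. Penk, which encodes the enkephalin precursor, had a log2 fold change of 1.48 (SE 0.33), from 36.2 ± 9.5 to 101.2 ± 52.6 CPM. Penk lay at 92.4, 53.6 and 157.7 CPM in methylphenidate replicates 1, 2 and 3, whose striatal list means were 0.75, -0.03 and 1.13, and is a gene of striatal neurons too. Trh, the member of smallest p, is also in the hypothalamic and basal forebrain list, and members shared with that list were not removed in any test. Nts and Tac1 had log2 fold changes of 1.53 (SE 0.50) and 0.55 (SE 0.22). The call was lost without saline replicates 1 or 3 or methylphenidate replicate 3 (camera adjusted p 0.0526 to 0.137), and the median was 0.15 without methylphenidate replicate 3. With no filter on low counts the median was 0.41. The hippocampal list, which contains Nnat, was higher with a median of 0.26 over 12 tested members, 7 of them above 0 and 5 below (camera adjusted p = 0.0495; adjusted p = 0.739 with an estimated correlation). Nnat alone passed over all genes tested, and 2 members were higher adjusted over the list alone. Wfs1, a gene of the endoplasmic reticulum, had a log2 fold change of 0.60 (SE 0.12). Its call was lost without saline replicates 1 or 3 or any one methylphenidate library (camera adjusted p 0.0629 to 0.337), and with upper-quartile scaling, total counts, no filter or a stricter filter (camera adjusted p 0.0513 to 0.0625). Its median was 0.45 without saline replicate 2 and 0.17 without methylphenidate replicate 2.

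The excitatory neuron list was lower, with a median log2 fold change of -0.16 over 10 tested members, 7 of them below 0 and 3 above (camera adjusted p = 0.0346; adjusted p = 0.739 with an estimated correlation), with no member past the threshold over all genes tested and 1 lower adjusted over the list alone. The upper-layer list was lower, with a median of -0.21 over 9 tested members, 8 of them below 0 (camera adjusted p = 0.0301; adjusted p = 0.739 with an estimated correlation), with none past the threshold over all genes tested, and 3 lower and 1 higher adjusted over the list alone. Cux1 and Rorb had log2 fold changes of -0.32 (SE 0.07) and -0.37 (SE 0.12), while Otof had one of 0.48 (SE 0.10). Both calls were lost without any one saline library and without methylphenidate replicates 1 or 3 (camera adjusted p 0.0525 to 0.168 for the excitatory list and 0.0575 to 0.150 for the upper-layer list). Without methylphenidate replicate 2 the excitatory median was -0.26. In the excitatory list, methylphenidate replicates 1 and 3, the libraries with the highest striatal list means, had list means of -0.10 and -0.18, and replicate 2 had 0.07.

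The voltage-gated potassium and sodium channel list was lower, with a median log2 fold change of -0.10 over 22 tested members, 18 of them below 0 (camera adjusted p = 0.0138; adjusted p = 0.739 with an estimated correlation). None passed over all genes tested, and 2 were lower adjusted over the list alone. Kcna1 and Scn1a had log2 fold changes of -0.32 (SE 0.08) and -0.34 (SE 0.11). The circadian clock list was lower, with a median of -0.14 over 18 tested members, 16 of them below 0 (camera adjusted p = 0.0138; adjusted p = 0.739 with an estimated correlation), and no member passed over all genes tested or adjusted over the list alone. Bhlhe40, a clock-controlled repressor gene, had a log2 fold change of -0.53 (SE 0.16). The channel call was lost without saline replicates 1 or 2 or methylphenidate replicate 3 (camera adjusted p 0.0506 to 0.0791), and the clock call without saline replicates 1 or 3 or methylphenidate replicate 1 (camera adjusted p 0.0526 to 0.246). The channel median was -0.06 without saline replicate 2.

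Oligodendrocyte precursor markers were higher, with a median log2 fold change of 0.22 over 10 tested members, 8 of them above 0 (camera adjusted p = 0.0084; adjusted p = 0.632 with an estimated correlation). No member passed over all genes tested or adjusted over the list alone. C1ql1 had a log2 fold change of 0.54 (SE 0.15), Pdgfra of 0.21 (SE 0.08) and Cspg4 of 0.37 (SE 0.14). Without saline replicate 2 the median was 0.15 and the adjusted p by camera 0.140. The cholesterol synthesis list was higher, with a median of 0.10 over 21 tested members, 20 of them above 0 (camera adjusted p = 0.0106; adjusted p = 0.739 with an estimated correlation), and again none passed over all genes tested or adjusted over the list alone. Srebf2, the regulator of the pathway, had a log2 fold change of 0.17 (SE 0.07). That call was lost without saline replicate 2 or methylphenidate replicate 2 (camera adjusted p 0.150 to 0.448), with medians of 0.05 and 0.06, and the median was 0.16 without saline replicate 3.

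**Figure D3:**
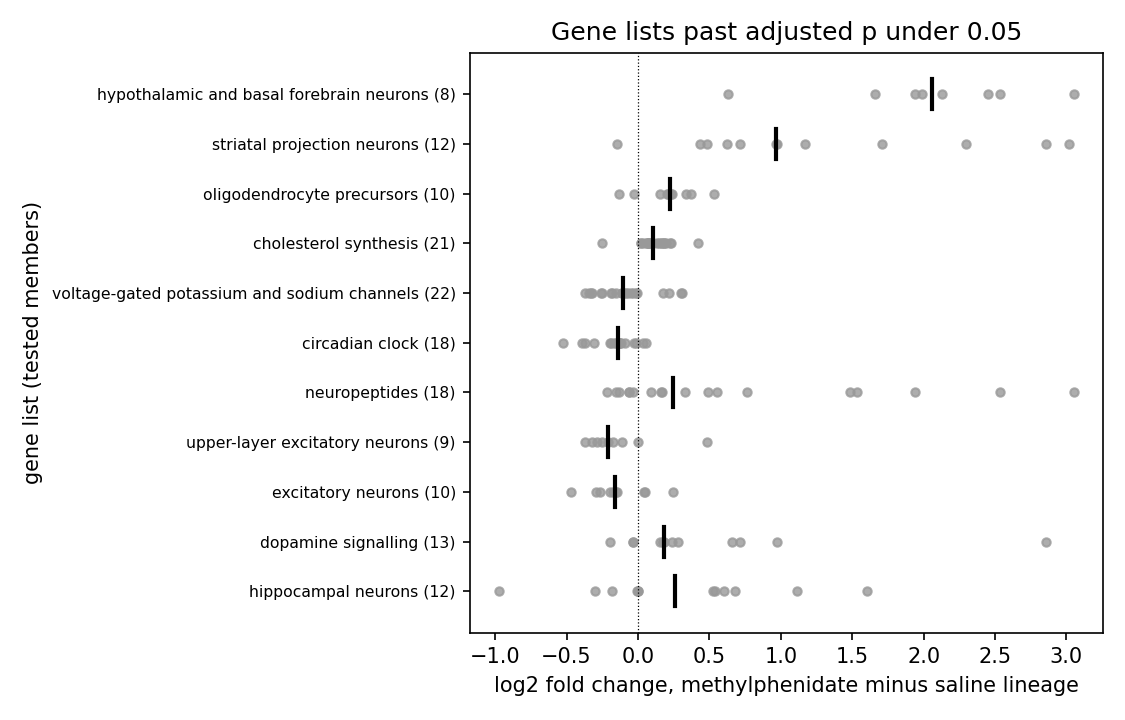
Log2 fold change (methylphenidate minus saline lineage) of the tested members of each of the 11 lists past the threshold, one grey point per gene, with the list median as a black bar and the number of tested members in brackets. The medians of the hypothalamic and striatal lists lie at 2.06 and 0.97, and those of the other 9 lists lie between -0.21 and 0.26.

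The other lists fixed for the treatment did not pass camera. The noradrenaline list had a median log2 fold change of 0.11 over 8 tested members (camera adjusted p = 0.892), none of them past the threshold over all genes tested or adjusted over the list alone, and Adra2c, an adrenergic receptor gene, had one of 0.46 (SE 0.14). The glutamate receptor list had a median of 0.09 over 22 members (camera adjusted p = 0.250). The GABA list had a median of 0.03 over 20 members (camera adjusted p = 0.963). The immediate early gene list had a median of -0.14 over 24 members (camera adjusted p = 0.107), with Ier5 at -0.53 (SE 0.10) and 1 member lower adjusted over the list alone, and it passed without saline replicate 2 (camera adjusted p = 0.00117) or methylphenidate replicate 2 (camera adjusted p = 0.000393). The DNA methylation enzyme list had a median of -0.01 over 16 members (camera adjusted p = 0.325), with Gadd45g at 0.47 (SE 0.18). The histone-modifying enzyme list had a median of 0.02 over 24 members (camera adjusted p = 0.856), with Hdac11 at 0.19 (SE 0.06). Over the fits without 1 library, the median of the immediate early list lay between -0.30 and -0.03, that of the glutamate list between 0.03 and 0.11, that of the DNA methylation list between -0.043 and -0.0032 and that of the imprinted list between 0.02 and 0.07. Those of the noradrenaline, GABA and histone lists went through 0 (-0.01 to 0.21, -0.02 to 0.04 and -0.02 to 0.05), so no direction is given for these 3. In the glutamate, GABA, DNA methylation and histone lists no member passed over all genes tested or adjusted over the list alone, and in the immediate early list none passed over all genes tested. The imprinted gene list had a median of 0.04 over 26 members (camera adjusted p = 0.121), and 2 members were higher adjusted over the list alone, while Nnat alone passed over all genes tested. Dlk1, a paternally expressed gene, had 0.782 ± 0.306 CPM in the saline and 3.60 ± 0.83 CPM in the methylphenidate lineage (SD, n = 3; edgeR adjusted p = 0.111), and Magel2 had a log2 fold change of 1.39 (SE 0.44, edgeR adjusted p = 0.522).

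Among the cell type lists that did not pass, microglia had a median of 0.07 (camera adjusted p = 0.0975), astrocytes of 0.10 (0.165), deep-layer excitatory neurons of -0.11 (0.327), inhibitory neurons of 0.05 (0.991), mature oligodendrocytes of -0.03 (0.670), endothelial cells of -0.01 (0.936), pericytes and vascular smooth muscle of -0.14 (0.200), fibroblasts of -0.05 (0.327), ependymal cells of 0.28 (0.866), thalamic neurons of 0.20 (0.325), erythrocytes of -0.13 (0.970), and olfactory bulb or cortical amygdala neurons of 0.19 (0.0555), each median given as log2 fold change with the camera adjusted p in brackets. Adjusted over the list alone, 1 member was higher in each of the microglia, thalamic and deep-layer lists and 3 in the olfactory bulb or cortical amygdala list, and none in the other lists of this group; none passed over all genes tested. For the inhibitory neuron list the test direction was down while the median was above 0. The choroid plexus list had a median of -0.69 (camera adjusted p = 0.309), and its marker Ttr, chosen after its values were seen, had 957, 15000 and 9089 counts in the saline libraries and 11075, 5052 and 408 in the methylphenidate libraries. Without saline replicate 1 the choroid plexus list passed (median -1.20, camera adjusted p = 0.000165), and over the 6 fits without 1 library its median lay between -1.30 and -0.01. Over the same fits the medians went through 0 for ependymal cells (-0.07 to 0.35), thalamic neurons (-0.01 to 0.30), erythrocytes (-0.43 to 0.33), microglia (-0.03 to 0.14), deep-layer neurons (-0.16 to 0.02), fibroblasts (-0.17 to 0.06), mature oligodendrocytes (-0.14 to 0.12), endothelial cells (-0.06 to 0.05) and inhibitory neurons (-0.04 to 0.07), and no direction is given for these lists. They lay between 0.05 and 0.18 for astrocytes, -0.23 and -0.03 for pericytes and vascular smooth muscle, and 0.12 and 0.35 for olfactory bulb or cortical amygdala neurons. Microglia passed without methylphenidate replicates 1 or 2 (camera adjusted p 0.0330 and 0.0389), astrocytes and fibroblasts without methylphenidate replicate 2 (0.0121 and 0.00701) and mature oligodendrocytes without saline replicate 2 (0.0369). Blood leukocytes had 1 tested member and no test was made.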

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

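The striatal covariate and the removal of members shared with the striatal list were chosen after the data were seen, and the other alternatives before. Under no alternative run did any called gene or list change sign. The count of 5 genes was 10 by total count alone, 3 without a filter, 16 with the robust edgeR fit, 149 with DESeq2, 11 at an adjusted p under 0.1 and 1376 at an unadjusted p under 0.05, and it was 2 with the striatal list mean as a covariate, of which 1 was among the 5. Except for the different threshold or the fewer degrees of freedom, the cause was not tested. Leaving out 1 library gave 2 to 26 genes. The count stayed at 5 with the other scalings, the stricter filter, limma-voom, the older edgeR fit, at least a 1.5-fold change and without mitochondrially encoded genes. Of the 45 lists tested, 0 passed with an estimated correlation, 2 by fry, neither of them among the 11 of the main test, and 17 by cameraPR, with all 11 among them. With the stricter filter the hypothalamic list had too few tested members to give a value. Leaving out 1 library gave 5 to 16 lists, and the lists without members shared with the striatal list gave 8, without the striatal list itself, the dopamine list and the hippocampal list, which shares no member with it. The replicate numbers shared by the groups did not pair the samples: the correlation of same-numbered deviations was -0.04, 0.09 and -0.02, and only number 2 correlated best with its own number. With a replicate block, 2 genes, Firre and Nnat, and 11 lists passed, 10 of them among the 11 and the hippocampal list not, with the serotonin list gained (camera adjusted p = 0.0286), while Cpne7, Hap1 and H2-T23 had edgeR adjusted p of 0.0729, 0.0729 and 0.159. Of 1437 values of 80 named genes under the alternatives, 20 of genes that did not pass changed sign. Of genes that did not pass, 27 values newly passed the threshold, and of called genes 22 values no longer did. The transporter genes lay below the expression filter, and whether depth or the tissue limited them and other genes near the filter was not tested.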

Other observations

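The test on a second striatal list and both counts of other splits were set before their results were seen; the tests of within-group covariation, the striatal covariate, the hypothalamic peptides, the dilution of Firre, the Firre neighbours and the on-off genes were chosen after, and the rules of the covariate and on-off tests were rewritten once after a first result (the covariate test gave 5 of 5 genes under both rules).

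Serotonin receptor genes were among the members of smallest p in a list that camera did not call (camera adjusted p = 0.0555) and fry did (fry adjusted p = 0.00991). Its median log2 fold change was 0.11, with 9 of 13 members above 0 and 4 below, and it also passed camera without a filter on low counts (camera adjusted p = 0.0406) and cameraPR (adjusted p = 0.0295), but not with an estimated correlation (adjusted p = 0.632). It passed in none of the 6 fits without 1 library (median 0.06 to 0.29, camera adjusted p 0.0507 to 0.143). Htr1d, Htr1a and Htr2c had log2 fold changes of 1.85 (SE 0.50), 0.40 (SE 0.11) and 0.63 (SE 0.20), none past the threshold over all genes tested, and 3 of 13 members were higher adjusted over the list alone. Baiap3, in the olfactory bulb or cortical amygdala list, had a log2 fold change of 2.18 (SE 0.30, edgeR adjusted p = 0.0703), from 3.44 ± 1.52 to 15.6 ± 1.8 CPM. Nr2f2, of the same list, had a log2 fold change of 0.99 (SE 0.21), and Calb2, of the thalamic list, one of 0.84 (SE 0.18). Of the 13 other pathway lists not yet given, from presynaptic release to oxidative phosphorylation, camera adjusted p lay between 0.0972 and 0.991. Without 1 library, 4 of them passed: presynaptic release, acetylcholine and histamine receptors and ribosomal proteins without methylphenidate replicate 2 (camera adjusted p 0.0304, 0.0200 and 0.0121), and heat shock without saline replicates 2 or 3 (0.0374 and 0.0482). In the inflammatory and mitochondrially encoded lists the median lay below 0 while the test direction was up. Pomc, the precursor of melanocortin peptides and chosen after its values were seen, had 471 counts in methylphenidate replicate 3 and 36 to 66 in the other libraries. It is a member of the hypothalamic and basal forebrain list, and its higher level in the methylphenidate lineage rests on that library.

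With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be had. The real split gave 5 genes and the highest of the other splits 7, and 2 of the 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 1376 genes and the highest of the others 1091. The real split gave 11 lists and the highest of the others 16, and 3 of the 10 splits gave as many.

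The first pattern is the higher striatal list. Striatal tissue carried into the dissection is a candidate explanation. A second list held 14 striatal genes, of which 12 were tested and 11 lay above 0. Its median log2 fold change was 0.26, at percentile 100 of 10000 random lists matched on expression. The random genes were drawn singly, so that percentile does not allow for correlation between the members. None of the 12 tested members passed adjusted over the list alone. The deviations of the striatal genes within groups had a mean pairwise correlation of 0.51, also at percentile 100. Lists of other genes reached as much, such as ribosomal proteins at 0.57, mature oligodendrocytes at 0.80 and choroid plexus at 0.94, while the GABA list had 0.20. The oligodendrocyte and choroid plexus lists hold cell type markers and may themselves vary with the tissue taken, which was not tested. The ribosomal list holds no such markers. A high correlation alone therefore does not single out carried-in tissue. Ppp1r1b and Pde10a had 113.2 and 49.9 CPM in the saline lineage against 186.1 and 112.2 in the methylphenidate lineage, while Foxp1 had a log2 fold change of -0.15 (SE 0.08), all 12 tested members had reads in saline-lineage cortex too, and an effect of the lineage on expression within cortical cells stays open and was not tested.

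The second pattern is the 5 called genes. Striatal tissue as their whole cause was examined with the striatal list mean of each library as a covariate. All 5 kept an unadjusted p under 0.05 and at least 0.5 of their log2 fold change. The 5 were called in these same libraries, where a small spread within groups favours a call. The covariate could therefore hardly remove them, and the test does not decide the question. Nnat went from 1.11 (SE 0.10) to 1.35 (SE 0.16), Cpne7 from 1.00 (SE 0.10) to 1.19 (SE 0.17), H2-T23 from 2.10 (SE 0.24) to 2.16 (SE 0.42), Hap1 from 0.93 (SE 0.11) to 0.95 (SE 0.19) and Firre from -4.27 (SE 0.24) to -3.57 (SE 0.30), but with the larger errors and 1 term more only Firre stayed past the threshold (edgeR adjusted p = 0.0105; the others 0.0690 to 0.847). For the 4 higher genes, tissue of the hypothalamus cannot be told apart from a lineage effect. Nnat and Cpne7 were highest in methylphenidate replicate 2 (119.3 and 54.2 CPM), whose hypothalamic list mean was the lowest of the 3 (0.26). Hap1 and H2-T23 were highest in methylphenidate replicate 3 (138.4 and 5.03 CPM), whose hypothalamic list mean was the highest (1.57). Hcrt, Pmch and Oxt together reached 25 counts in methylphenidate replicate 3 but 7 and 6 in replicates 1 and 2, against 0 to 5 in the saline libraries. Avp, from the list itself, had 36, 2 and 21 counts in the methylphenidate libraries against 0, 0 and 10 in the saline libraries. These peptides come from small nuclei that a dissection could miss. Tissue of further regions and differences between animals of this outbred stock were not tested as causes for these 4 genes. A lineage effect stays open and was not tested.

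The third pattern is the fall of Firre by 4.27 on the log2 scale, which hypothalamic tissue could give only by dilution, and this was argued against, since the excitatory neuron list, diluted alike, had a median of -0.16. Reads assigned to neighbouring genes were argued against too, for the 6 genes of the GENCODE M21 annotation within 500 kb. These gained 0.78 CPM, or 1.60% of the 48.7 CPM that Firre lost. Genes in the counts but not in that annotation were not covered. On-off expression that differs between animals of an outbred stock may also play a part, which the tables do not decide: of 19 genes with a gap of more than 2 on the log2 scale between 3 libraries and the other 3, Firre was the 1 that followed the groups (1.9 expected), and at gaps of 1, 1.5 and 3 there were 11 of 52, 4 of 27 and 1 of 11 (exact binomial p, one-sided, 0.0126, 0.282 and 0.686, and 0.865 at a gap of 2). The verdict turned on the gap chosen, a first form of this test used the gap of 2 alone, genes are not independent, and some on-off genes, such as Septin2, can reflect how reads were assigned. Firre lies on the X chromosome, which F1 sires receive from their untreated mothers and not from the treated grandsire. That goes against passage of this locus itself from the grandsire. Whether F2 animals shared a sire is not given in the sources used here. A lineage effect by another route stays open and was not tested.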
